A study of Mus musculus with 26 samples.

How the data were processed

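Total RNA was sequenced from bone marrow-derived dendritic cells of SKG mice in 26 libraries. Per the labels' protocols, lineage-depleted marrow was cultured in GM-CSF, stimulated, stained for CD11c and CD11b and sorted, and libraries were made with a kit that removes ribosomal RNA. The gates of the sort are not stated. The sample labels give 16 h of stimulation, whereas the protocol text gives 12 h. The labels number the mice but do not say whether the 3 stimulus groups shared animals, cultures or preparation days.

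The deposited count tables give, per the file headers, 1 raw count per gene symbol and library. Per the submitters' processing notes, reads were handled with Trimmomatic 0.36, HISAT2 2.2.1 and featureCounts of Subread 1.5.2 on the build GRCm38/mm10. Neither the strand setting nor the annotation release is stated. Antisense and overlapping genes, and genes with near-identical copies such as Rn7s1 and Rn7s2, Ifit3b, Oas1a, Iigp1, Apol9b, Ifi205 and the Slfn and Clec4 families, are therefore uncertain. The counts per library equalled those of the deposited count matrix of the series, with 0 differing values. The authors also deposited a table of CPM signal for 11307 genes, scaled per library. Of its 26 headings, 5 stood over values proportional to the counts of the library they name and 21 stood over another library's. The comparison used the 10846 genes with at least 50 counts in all. That table served only as an alternative, with limma's trend on its log2 values.

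Genes were tested in R 4.3.3 with edgeR 4.0.16. Of 50584 symbols, 18747 passed filterByExpr by group (minimum count 10, minimum total 15), and they held 99.98% of the counts. TMM factors lay between 0.82 and 1.24, and the common biological coefficient of variation was 0.154. A quasi-likelihood model with 1 mean per group over all 26 libraries, with 20 residual degrees of freedom, gave 11 contrasts. These were each stimulus against unstimulated cells in PBS and in RA mice, RA against PBS mice in each condition, the 2 differences between those responses, and poly(I:C) against beta-glucan in each kind of mouse. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 fold changes came from the quasi-likelihood F statistic. Levels of genes are CPM of TMM-scaled library sizes, except those of Malat1 and the small RNAs such as Rn7s1, which are CPM of library totals. Ratios to few or no unstimulated counts, their intervals and floors of 3 counts over a group also rest on library totals. Those intervals and floors cover counting error only and take counts as independent.

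The 27 gene lists were written before the data were examined, as were the groups, the contrasts, the other settings and the rule for naming genes. The lists were interferon-stimulated genes, nucleic acid sensing, inflammatory cytokines, NF-kB feedback genes, chemokines, dendritic cell maturation, MHC class I presentation, MHC class II presentation, C-type lectin pathway, inflammasome, alternative activation, glycolysis, oxidative phosphorylation, cholesterol synthesis, cholesterol efflux and lysosomal lipid handling, cell cycle, unfolded protein response, osteoclast genes, macrophage markers, dendritic cell identity, neutrophil and granulocyte precursor markers, monocyte and myeloid progenitor markers, mast cell and basophil markers, T and NK cell markers, B cell markers, fibroblast and stromal markers and erythroid markers. A list needed 3 tested members, which left 26, since 1 of 12 erythroid markers passed the filter. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, again with a correlation estimated from the data, and with fry, which asks whether a list's genes move on balance one way. Of 286 camera tests, 119 passed with the preset correlation and 23 with the estimated one, and fry passed 125. The 23 were all against unstimulated cells, namely the interferon-stimulated genes, cytokines, NF-kB feedback genes, chemokines and maturation genes in all 4 stimulus contrasts and nucleic acid sensing in 3 of them.

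Genes named for a contrast were, by that rule, the 10 largest rises and the 10 largest falls among called genes with a mean log2 CPM of at least 1, up to 4 members with the smallest p in each list that passed camera, and 18 anchor genes whatever their p. Names were dropped from the end of each ranking where space required. Of the 20 largest changes in a comparison, 18 to 20 had groups that did not overlap, but these genes were picked for large changes, so the share chance gives an unselected gene (2.86%, 1.59% or 0.794%) is no baseline. Symbols matched the reference annotation once for 47552 of 50584 symbols (94.0%), with the same span for 92.4% of the matched ones.

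The edgeR procedure was tested on simulated counts for the 18747 genes, with 200 changed. For RA against PBS in unstimulated cells it recovered 61.8%, 89.4% and 100% of genes changed by 0.5, 1 and 2 on the log2 scale, and 6.7% of its calls were unchanged genes. For the difference between beta-glucan responses it recovered 29.4%, 81.8% and 98.5%, with 4.1% unchanged among its calls. DESeq2 1.42.0 called 35 unchanged genes in the first setting, 16.7% of its calls, so its higher counts there are not better supported. With no change simulated, edgeR called 0 genes for RA against PBS under beta-glucan.

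Settings varied from the start were DESeq2 size factors or library totals in place of TMM, the DESeq2 Wald test, limma-voom with and without sample quality weights, other filters on low counts, only the groups compared, replicate numbers or triples of consecutive mouse numbers as blocks, other thresholds, the deposited CPM table, removal of ribosomal protein, haemoglobin and mitochondrial genes, and each library left out. Replicate numbers were read as pairs only where every pair of profiles correlated above 0.1. Over the 11619 genes with a mean log2 CPM of at least 1 this held for poly(I:C) against beta-glucan in PBS mice alone (r from 0.18 to 0.66 across genes, which are not independent replicates). Over all genes it held nowhere (r 0.06 to 0.22 there). By mouse triple over those 11619, median r with unstimulated RA cells was 0.19 for beta-glucan and 0.28 for poly(I:C) (both -0.08 by replicate). This check's gene set and the log2 CPM slopes were chosen after seeing the data. So were leaving out mouse numbers 43 to 45 and a library's Malat1 or small RNA share as covariate.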

Results

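RNA sequencing was carried out on GM-CSF-grown bone marrow dendritic cells of SKG mice, a BALB/c line prone to autoimmune arthritis because of a mutation in the T-cell kinase gene Zap70. RA mice had received zymosan, a yeast cell wall preparation (5 mg per mouse), and PBS mice the vehicle, at least 5 weeks before marrow was taken. Cultures were given beta-glucan (5 ug/mL), a ligand of the lectin receptor Clec7a, poly(I:C) (20 ug/mL), a mimic of double-stranded RNA sensed by Tlr3 and Ifih1, or PBS. The PBS mice gave 4 unstimulated, 4 beta-glucan and 4 poly(I:C) libraries, and the RA mice 4, 5 and 5. Total counts lay between 52.0 and 80.8 M (mega) per library, with means of 66.1, 69.7 and 69.5 M in the PBS groups and 64.4, 64.3 and 65.2 M in the RA groups, in the same order. Zap70 itself had 0 to 10 counts per library. Mouse numbers ran from 19 to 33 in PBS mice and from 34 to 48 in RA mice, so any difference between the injections was confounded with whatever else changed between those ranges. The study asked how trained immunity, a lasting change of innate cells after an earlier stimulus, altered these transcriptomes. Values after gene names are log2 fold changes ± SE, and the largest rises and falls are those among genes with a mean log2 CPM of at least 1.

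In PBS mice, beta-glucan raised cytokine and interferon-stimulated genes. The interleukin gene Il6 (ENSMUSG00000025746.11, chromosome 5, 30013114 to 30019981, GRCm38/mm10) went from 2.11 ± 0.975 to 429 ± 29.5 CPM (SD, n = 4 each; 7.66 ± 0.26, edgeR adjusted p = 7.77e-19). Dll4, a Notch ligand with 6 counts over the 4 unstimulated libraries, had the largest fitted rise at that level (10.73 ± 0.54). It was followed by Enpp2 (10.26 ± 0.21), which makes lysophosphatidic acid, the plasminogen activator gene Plat (9.45 ± 0.37), the inducible cyclooxygenase gene Ptgs2 (9.45 ± 0.28), Col5a3 (9.04 ± 0.40) and Dusp14 (8.59 ± 0.29). The galactose lectin gene Clec10a (ENSMUSG00000000318.16, chromosome 11, 70156197 to 70170834) fell furthest at that level, from 48.9 ± 9.93 to 0.799 ± 0.0524 CPM (-5.93 ± 0.23, edgeR adjusted p = 9.36e-18). Next came the Rac regulator Chn2 (-5.39 ± 0.23), Pald1 (-4.97 ± 0.19), the creatine kinase gene Ckb (-4.80 ± 0.23), the corepressor Hr (-4.59 ± 0.15) and Ccr2 (-4.54 ± 0.22), the receptor of monocyte chemoattractants.

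Among the interferon-stimulated genes, 31 of 31 rose (31 adjusted over the list alone, median 2.57, camera adjusted p = 2.7e-48). Stat1 (2.61 ± 0.07) and Xaf1 (2.53 ± 0.07) led. Of the nucleic acid sensing genes, 11 rose and 4 fell of 17 (11 and 4 adjusted over the list alone, median 1.09, camera adjusted p = 2.99e-06, 0.0726 with an estimated correlation). Dhx58 (2.15 ± 0.07) and Zbp1 (2.42 ± 0.09) came first. Of the inflammatory cytokines, 18 of 20 rose (18 adjusted over the list alone, median 4.78, camera adjusted p = 1.45e-20). Examples were Il1a (5.89 ± 0.21), Il1b (5.51 ± 0.22) and Il12b (6.71 ± 0.27). With the genes without unstimulated counts set at their bounds the cytokine median was 3.92. Of the NF-kB feedback genes, 18 of 18 rose (18 adjusted over the list alone, median 1.88, camera adjusted p = 3.42e-23). Examples were Tnfaip3 (2.45 ± 0.09) and Nfkbiz (2.36 ± 0.09). Of the chemokines, 16 rose and 2 fell of 19 (16 and 2 adjusted over the list alone, median 3.33, camera adjusted p = 1.68e-14). Ccl5 (5.38 ± 0.15) and Cxcl9 (5.84 ± 0.19) came first. Among the dendritic cell maturation genes, 16 rose and 1 fell of 17 (16 and 1 adjusted over the list alone, median 2.37, camera adjusted p = 2.45e-19). Examples were Cd200 (4.54 ± 0.13) and Slamf1 (5.16 ± 0.17). Of the MHC class I presentation genes, 15 of 16 rose (15 adjusted over the list alone, median 1.27, camera adjusted p = 4.9e-10, 0.139 with an estimated correlation). Examples were H2-Q4 (1.65 ± 0.09) and Tap1 (1.39 ± 0.08). In the alternative activation list, which marks interleukin-4-type macrophages, 4 rose and 10 fell of 15 (4 and 10 adjusted over the list alone, median -1.06, camera adjusted p = 0.0143, 0.4 with an estimated correlation), with Ptgs1 (-4.27 ± 0.22) and Mgl2 (-3.58 ± 0.19) after Clec10a. Of the cell cycle genes, 1 rose and 25 fell of 26 (1 and 25 adjusted over the list alone, median -2.13, camera adjusted p = 4.99e-15, 0.0623 with an estimated correlation). Examples were Mcm7 (-2.38 ± 0.11) and Ccna2 (-3.03 ± 0.15).

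Other anchor genes that rose with beta-glucan in PBS mice were Tnf (2.38 ± 0.15), Cxcl10 (5.09 ± 0.23), Isg15 (5.38 ± 0.18), Nos2 (8.13 ± 0.39), Cd86 (2.14 ± 0.12), Cd40 (3.82 ± 0.18), Ccr7 (2.93 ± 0.18), Clec7a (0.65 ± 0.10), Tlr3 (0.59 ± 0.19) and Ifih1 (2.21 ± 0.08). Il10 had 2 counts over the unstimulated libraries, and its ratio was 878 (95% counting interval 243 to 7260). Ifnb1 had none and was at least 12-fold higher, against a floor of 3 counts over the group. Arg1 (0.77 ± 0.51) and H2-Ab1 (-0.19 ± 0.13) did not pass. In all, 5636 genes rose and 5831 fell and 12039 had an unadjusted p under 0.05. With library totals in place of TMM the median of all genes shifted by -0.27, and 3862 rose and 8183 fell.

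**Figure D1:**
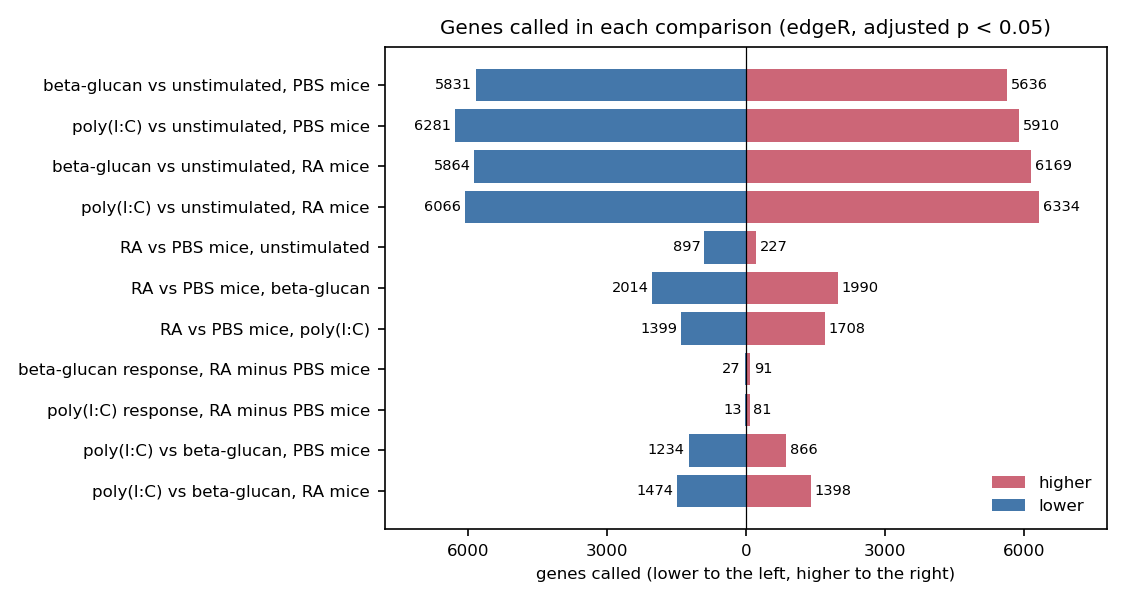
Numbers of genes called higher (right) and lower (left) in each of the 11 comparisons by edgeR at an adjusted p under 0.05. Both stimuli changed over 11000 genes in either kind of mouse, RA and PBS mice differed in 1124 to 4004 genes, and 118 and 94 genes responded differently.

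With poly(I:C) in PBS mice, Dll4 (10.82 ± 0.54), Plat (9.59 ± 0.37), Ptgs2 (9.54 ± 0.28), Enpp2 (9.41 ± 0.21), Dusp14 (8.81 ± 0.29) and Col5a3 (8.51 ± 0.39) rose most, the first from 6 counts, followed by Itgb8 (8.30 ± 0.28), Rsad2 (8.16 ± 0.31) and Il12b (7.97 ± 0.29), of which Rsad2 codes for the antiviral viperin. Clec10a (-6.91 ± 0.25), Chn2 (-6.55 ± 0.25), Ckb (-6.16 ± 0.25), Pald1 (-5.96 ± 0.20), Hr (-5.93 ± 0.16), Mrc1 (-5.92 ± 0.26), Ccr2 (-5.75 ± 0.24) and Il18rap (-5.67 ± 0.18) fell most, of which Mrc1 codes for the mannose receptor and Il18rap for a chain of the interleukin-18 receptor. Clec10a had 0.407 ± 0.203 CPM left, and Il6 reached 461 ± 60.6 CPM (SD, n = 4; 7.76 ± 0.26, edgeR adjusted p = 4.14e-19). The interferon-induced chemokine gene Cxcl10 (ENSMUSG00000034855.13, chromosome 5, 92346638 to 92348889) went from 1.27 ± 0.234 to 202 ± 39.5 CPM, against 43.3 ± 4.99 under beta-glucan (7.31 ± 0.25 for poly(I:C), edgeR adjusted p = 5.58e-19).

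Of the interferon-stimulated genes, 31 of 31 rose (31 adjusted over the list alone, median 2.99, camera adjusted p = 6.28e-54). Stat1 (2.93 ± 0.07), Xaf1 (3.04 ± 0.08) and Oasl1 (5.57 ± 0.14) came first. Of the nucleic acid sensing genes, 11 rose and 3 fell of 17 (11 and 4 adjusted over the list alone, median 1.24, camera adjusted p = 1.76e-07). Dhx58 (2.49 ± 0.07) and Ifih1 (2.86 ± 0.08) led. Among the inflammatory cytokines, 20 of 20 rose (20 adjusted over the list alone, median 4.62, camera adjusted p = 3.37e-19), and among the NF-kB feedback genes, 18 of 18 rose (18 adjusted over the list alone, median 1.89, camera adjusted p = 4.33e-20). Of the chemokines, 15 rose and 3 fell of 19 (15 and 3 adjusted over the list alone, median 3.01, camera adjusted p = 2.4e-12). Ccl5 (6.41 ± 0.16) and Cxcl9 (5.92 ± 0.19) came first. Of the dendritic cell maturation genes, 16 of 17 rose (16 adjusted over the list alone, median 2.55, camera adjusted p = 3.37e-19). Examples were Cd200 (4.82 ± 0.14) and Slamf1 (4.99 ± 0.17). Among the MHC class I presentation genes, 15 of 16 rose (15 adjusted over the list alone, median 1.46, camera adjusted p = 1.47e-11, 0.0949 with an estimated correlation). Of the C-type lectin pathway genes, 4 rose and 8 fell of 15 (4 and 8 adjusted over the list alone, median -1.11, camera adjusted p = 0.0247, 0.714 with an estimated correlation), with Clec4a2 (-3.65 ± 0.20) and Card9 (-1.58 ± 0.09) after Mrc1. In the alternative activation list 4 rose and 10 fell of 15 (4 and 10 adjusted over the list alone, median -1.55, camera adjusted p = 0.0101, 0.349 with an estimated correlation). Of the cell cycle genes, 1 rose and 25 fell of 26 (1 and 25 adjusted over the list alone, median -2.28, camera adjusted p = 1.16e-13, 0.0673 with an estimated correlation). Mcm7 (-2.43 ± 0.11) and Ccna2 (-3.13 ± 0.15) led. Of the monocyte and myeloid progenitor markers, 5 rose and 10 fell of 15 (5 and 10 adjusted over the list alone, median -2.26, camera adjusted p = 0.0392, 0.284 with an estimated correlation). Spn (-3.76 ± 0.14) came first.

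Anchor genes not yet named for poly(I:C) in PBS mice were Tnf (2.05 ± 0.15), Il1b (5.52 ± 0.22), Isg15 (6.01 ± 0.18), Nos2 (7.84 ± 0.38), Cd86 (2.55 ± 0.13), Cd40 (4.49 ± 0.19), Ccr7 (3.13 ± 0.18) and Tlr3 (0.96 ± 0.19), all of which rose. Il10 had a ratio of 129 (95% counting interval 35.5 to 1070) and Ifnb1 was at least 40.6-fold higher. Arg1 (0.44 ± 0.51), H2-Ab1 (-0.03 ± 0.13) and Clec7a (0.18 ± 0.10) did not pass. Genes that rose numbered 5910 and those that fell 6281. With library totals the median shifted by -0.35, and 3792 rose and 8989 fell.

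With beta-glucan in RA mice, Ptgs2 (9.88 ± 0.28), Col5a3 (9.54 ± 0.42), Enpp2 (9.24 ± 0.20), Nos2 (8.81 ± 0.39), Itgb8 (8.62 ± 0.29), U90926 (8.44 ± 0.61), Plat (8.34 ± 0.34) and Dll4 (8.01 ± 0.47) rose most, of which Nos2 makes nitric oxide. Chn2 (-5.65 ± 0.21), Clec10a (-5.47 ± 0.21), Asgr2 (-4.91 ± 0.23), Ckb (-4.81 ± 0.22), Pald1 (-4.74 ± 0.17), Ccr2 (-4.65 ± 0.20), Hr (-4.61 ± 0.14) and Ptpn22 (-4.60 ± 0.16) fell most, of which Ptpn22 codes for a phosphatase of antigen-receptor signalling. Il6 went from 4.84 ± 1.3 (n = 4) to 653 ± 95.1 CPM (n = 5; 7.08 ± 0.25, edgeR adjusted p = 9.01e-19).

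Of the interferon-stimulated genes, 31 of 31 rose (31 adjusted over the list alone, median 2.92, camera adjusted p = 1.16e-51). Stat1 (2.57 ± 0.07) and Xaf1 (2.55 ± 0.07) led. Of the nucleic acid sensing genes, 13 rose and 3 fell of 17 (13 and 3 adjusted over the list alone, median 1.24, camera adjusted p = 5.8e-08). Among the inflammatory cytokines, 20 of 20 rose (20 adjusted over the list alone, median 4.56, camera adjusted p = 2.04e-20), and among the NF-kB feedback genes, 18 of 18 rose (18 adjusted over the list alone, median 1.89, camera adjusted p = 8e-22). Of the chemokines, 15 rose and 3 fell of 19 (15 and 3 adjusted over the list alone, median 3.66, camera adjusted p = 1.2e-14), and of the dendritic cell maturation genes, 16 rose and 1 fell of 17 (16 and 1 adjusted over the list alone, median 2.40, camera adjusted p = 3.83e-18). Of the MHC class I presentation genes, 15 of 16 rose (15 adjusted over the list alone, median 1.42, camera adjusted p = 1.55e-12, 0.0787 with an estimated correlation). Tap1 (1.85 ± 0.07) came first. In the inflammasome list 7 rose and 2 fell of 12 (7 and 2 adjusted over the list alone, median 0.54, camera adjusted p = 0.0451, 0.64 with an estimated correlation). Casp4 (3.09 ± 0.09), Casp1 (1.66 ± 0.11) and Mefv (2.07 ± 0.18) came first, and Mefv codes for pyrin. In the glycolysis list 12 of 16 rose (12 adjusted over the list alone, median 0.61, camera adjusted p = 0.00541, 0.64 with an estimated correlation), led by Pfkfb3 (3.26 ± 0.17) and Gapdh (1.93 ± 0.11), and Pfkfb3 makes the sugar phosphate that activates phosphofructokinase. In the oxidative phosphorylation list 2 rose and 14 fell of 20 (2 and 14 adjusted over the list alone, median -0.43, camera adjusted p = 0.0342, 0.76 with an estimated correlation). Atp5o (-0.97 ± 0.08) and Cox7b (-0.79 ± 0.07) led. In the alternative activation list 4 rose and 10 fell of 15 (4 and 10 adjusted over the list alone, median -0.83, camera adjusted p = 0.0404, 0.592 with an estimated correlation), and of the cell cycle genes, 1 rose and 22 fell of 26 (1 and 22 adjusted over the list alone, median -1.91, camera adjusted p = 1.64e-12, 0.0787 with an estimated correlation).

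Other anchors that rose with beta-glucan in RA mice were Tnf (2.64 ± 0.15), Il1b (5.01 ± 0.21), Il12b (6.11 ± 0.26), Il10 (9.14 ± 0.45), Ifnb1 (3.09 ± 0.58), Cxcl10 (5.61 ± 0.23), Isg15 (5.15 ± 0.17), Ccl5 (5.59 ± 0.15), Arg1 (1.48 ± 0.50), Cd86 (2.16 ± 0.12), Cd40 (4.20 ± 0.18) and Ccr7 (2.89 ± 0.17), and Ifnb1 and Il10 rested on 8 and 7 unstimulated counts. H2-Ab1 (0.15 ± 0.12) and Clec7a (-0.07 ± 0.09) did not pass. Of 12033 genes called, 6169 rose and 5864 fell. With library totals the median shifted by -0.39, and 3632 rose and 9201 fell.

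Under poly(I:C) in RA mice Ptgs2 (9.69 ± 0.28), Itgb8 (9.13 ± 0.29), Col5a3 (9.07 ± 0.41), Rsad2 (8.56 ± 0.31), Plat (8.45 ± 0.34), Dll4 (8.38 ± 0.47), Nos2 (8.31 ± 0.39) and Enpp2 (8.24 ± 0.19) rose most, and Clec10a (-6.16 ± 0.22), Chn2 (-5.92 ± 0.22), Hr (-5.76 ± 0.15), Pald1 (-5.68 ± 0.18), Ckb (-5.47 ± 0.23), Asgr2 (-5.40 ± 0.24), Ccr2 (-5.26 ± 0.21) and Il18rap (-5.14 ± 0.16) fell most. Il6 reached 672 ± 53.3 CPM (SD, n = 5; 7.12 ± 0.25), Cxcl10 went from 1.92 ± 0.48 to 422 ± 131 CPM, and Clec10a fell to 0.564 ± 0.187 CPM (edgeR adjusted p = 6.97e-19). Of the interferon-stimulated genes, 31 of 31 rose (31 adjusted over the list alone, median 3.20, camera adjusted p = 3.32e-56). Stat1 (2.93 ± 0.07) and Oasl1 (5.46 ± 0.14) came first. Of the nucleic acid sensing genes, 12 rose and 2 fell of 17 (12 and 2 adjusted over the list alone, median 1.46, camera adjusted p = 2.24e-09). Of the inflammatory cytokines, 20 of 20 rose (20 adjusted over the list alone, median 4.99, camera adjusted p = 6.36e-20), and of the NF-kB feedback genes, 18 of 18 rose (18 adjusted over the list alone, median 1.87, camera adjusted p = 3.91e-20). Among the chemokines, 16 rose and 3 fell of 19 (16 and 3 adjusted over the list alone, median 3.47, camera adjusted p = 3.7e-13). Among the dendritic cell maturation genes, 17 of 17 rose (17 adjusted over the list alone, median 2.64, camera adjusted p = 7.12e-20). Among the MHC class I presentation genes, 15 of 16 rose (15 adjusted over the list alone, median 1.61, camera adjusted p = 7.77e-15, 0.0508 with an estimated correlation). In the inflammasome list 7 rose and 2 fell of 12 (7 and 2 adjusted over the list alone, median 0.57, camera adjusted p = 0.0294, 0.691 with an estimated correlation). Casp4 (3.36 ± 0.09) and Casp1 (1.92 ± 0.11) came first. In the glycolysis list 10 of 16 rose (10 adjusted over the list alone, median 0.44 and -0.04 with library totals, camera adjusted p = 0.0358, 0.82 with an estimated correlation). In the alternative activation list 4 rose and 10 fell of 15 (5 and 10 adjusted over the list alone, median -1.06, camera adjusted p = 0.034, 0.504 with an estimated correlation). Of the cell cycle genes, 1 rose and 24 fell of 26 (1 and 24 adjusted over the list alone, median -2.11, camera adjusted p = 1.04e-13, 0.0565 with an estimated correlation).

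Anchors that also rose with poly(I:C) in RA mice were Tnf (2.51 ± 0.15), Il1b (5.00 ± 0.21), Il12b (7.28 ± 0.28), Il10 (7.10 ± 0.47), Ifnb1 (4.99 ± 0.56), Cxcl10 (7.77 ± 0.25), Isg15 (5.70 ± 0.18), Ccl5 (6.39 ± 0.16), Cd86 (2.66 ± 0.12), Cd40 (4.99 ± 0.19) and Ccr7 (3.22 ± 0.17). H2-Ab1 (0.35 ± 0.12) rose with TMM but had -0.13 with library totals. Clec7a (-0.42 ± 0.09) fell and Arg1 (1.03 ± 0.49) did not pass. Of 12400 genes called, 6334 rose and 6066 fell. With library totals the median shifted by -0.47, and 3527 rose and 9762 fell. Across genes called in either kind of mouse, which are not independent replicates, the slope of the RA on the PBS response was 0.953 for beta-glucan (r = 0.937 over 13403 genes). It was 0.925 for poly(I:C) (r = 0.946 over 13760 genes). With both responses on log2 CPM it was 0.967 and 0.939, and 0.926 to 1.001 and 0.898 to 0.96 for single RA libraries. Over 36 divisions of the PBS libraries into 2 equal sets, the response of 1 set on that of the other had median slopes of 0.949 and 0.953 (0.916 to 0.994 and 0.916 to 1.001), and the RA response on those same sets 0.939 and 0.919 (lower in 26 and 36 of the 36), so slopes under 1 arose without a difference in injection too. Of 10097 genes called in both under beta-glucan 10079 had the same sign, and 10817 of 10831 under poly(I:C).

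Whether an earlier zymosan injection left a mark on resting cells was asked by comparing RA with PBS mice without stimulation. The interferon-induced growth regulator gene Slfn4 (ENSMUSG00000000204.16, chromosome 11, 83175186 to 83190216) was raised in RA mice, at 95.1 ± 28 against 21.8 ± 5.29 CPM (SD, n = 4 each; 2.12 ± 0.27, edgeR adjusted p = 0.000111). Apol9b (2.07 ± 0.50), Rn7s2 (2.00 ± 0.32), Saa3 (1.75 ± 0.37), Rn7s1 (1.64 ± 0.26), Rhou (1.44 ± 0.29), Mefv (1.43 ± 0.20) and Rpph1 (1.28 ± 0.25) rose next, of which Saa3 codes for an acute-phase protein and Rn7s1, Rn7s2 and Rpph1 for small non-coding RNAs. The transcription factor gene Onecut2 (ENSMUSG00000045991.19, chromosome 18, 64340364 to 64398488) fell furthest at that level, to 2.01 ± 0.276 from 8.44 ± 2.45 CPM (-2.07 ± 0.28, edgeR adjusted p = 0.000141). It was followed by Tnfrsf11b, the gene of the osteoclast inhibitor osteoprotegerin, at -1.80 ± 0.25, and by Tnfrsf13c (-1.48 ± 0.36), Itgb8 (-1.43 ± 0.30), Sema4f (-1.40 ± 0.32), Itgae (-1.37 ± 0.22) and Cd72 (-1.34 ± 0.18), of which Itgae codes for CD103.

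Among the interferon-stimulated genes, 13 rose and 0 fell of 31 (20 and 1 adjusted over the list alone, median 0.42, camera adjusted p = 1.07e-18, 0.279 with an estimated correlation). Examples were Xaf1 (0.54 ± 0.07), Oasl2 (0.70 ± 0.10) and Irf7 (0.72 ± 0.12). Of the inflammatory cytokines, 4 rose and 0 fell of 20 (5 and 2 adjusted over the list alone, median 0.10, camera adjusted p = 0.00806, 0.415 with an estimated correlation). Examples were Il6 (1.18 ± 0.22), Il1a (0.91 ± 0.18), Il15 (0.50 ± 0.10) and Il1b (0.88 ± 0.18). Of the chemokines, 5 rose and 0 fell of 19 (7 and 1 adjusted over the list alone, median 0.37, camera adjusted p = 5.4e-06, 0.398 with an estimated correlation). Cxcl2 (0.89 ± 0.17) and Cxcl9 (1.05 ± 0.20) came first. In the inflammasome list 2 of 12 rose (2 adjusted over the list alone, median 0.16, camera adjusted p = 0.000856, 0.45 with an estimated correlation), Mefv and Casp4 (0.48 ± 0.09). Of the MHC class II presentation genes, 6 of 13 fell (10 adjusted over the list alone, median -0.35, camera adjusted p = 1.11e-09, 0.279 with an estimated correlation). Ciita (-0.81 ± 0.12) and H2-Ob (-0.99 ± 0.15) came first, and Ciita is the master regulator of class II genes. Of the dendritic cell maturation genes, 0 rose and 4 fell of 17 (2 and 10 adjusted over the list alone, median -0.26, camera adjusted p = 0.00251, 0.504 with an estimated correlation). Examples were Il4i1 (-0.60 ± 0.14) and Cd200 (-0.48 ± 0.12). Of the dendritic cell identity genes, 1 rose and 4 fell of 16 (1 and 6 adjusted over the list alone, median -0.20, camera adjusted p = 0.0352, 0.44 with an estimated correlation). Kmo (-0.73 ± 0.15) and Btla (-1.04 ± 0.21) came first. Of the macrophage markers, 0 rose and 1 fell of 16 (1 and 3 adjusted over the list alone, median -0.11, camera adjusted p = 0.855). Of the 16 glycolysis genes, by edgeR 0 passed, 0 lay higher and 1 lower at an unadjusted p under 0.05, DESeq2 called 1 and limma-voom 0.

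Other anchors in resting cells were Isg15 (0.75 ± 0.16), which rose, and Cd86 (-0.42 ± 0.12) and H2-Ab1 (-0.43 ± 0.13), which fell. Tnf (-0.09 ± 0.15), Il12b (-0.22 ± 0.22), Cxcl10 (0.61 ± 0.24), Ccl5 (0.37 ± 0.13), Arg1 (0.62 ± 0.51), Nos2 (0.27 ± 0.30), Cd40 (-0.49 ± 0.16), Ccr7 (-0.40 ± 0.16) and Clec7a (0.29 ± 0.10) did not pass. Il10 and Ifnb1 had 2 and 0 counts over the PBS libraries and 7 and 8 over the RA libraries, and neither passed. By edgeR 227 genes rose and 897 fell, with 3689 at an unadjusted p under 0.05. That split moved with the scaling, to 441 and 431 with library totals, 458 and 896 with the Malat1 share as a covariate, and 114 and 121 with the small RNA share. The count of 1124 was 1707 with the DESeq2 Wald test, 2197 with only its groups and 2818 with voom quality weights. It fell to 519 without SKG_PBS_Unstim replicate 1 and to 562, 735 and 536 without SKG_RA_Unstim replicates 1, 2 and 3.

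**Figure D2:**
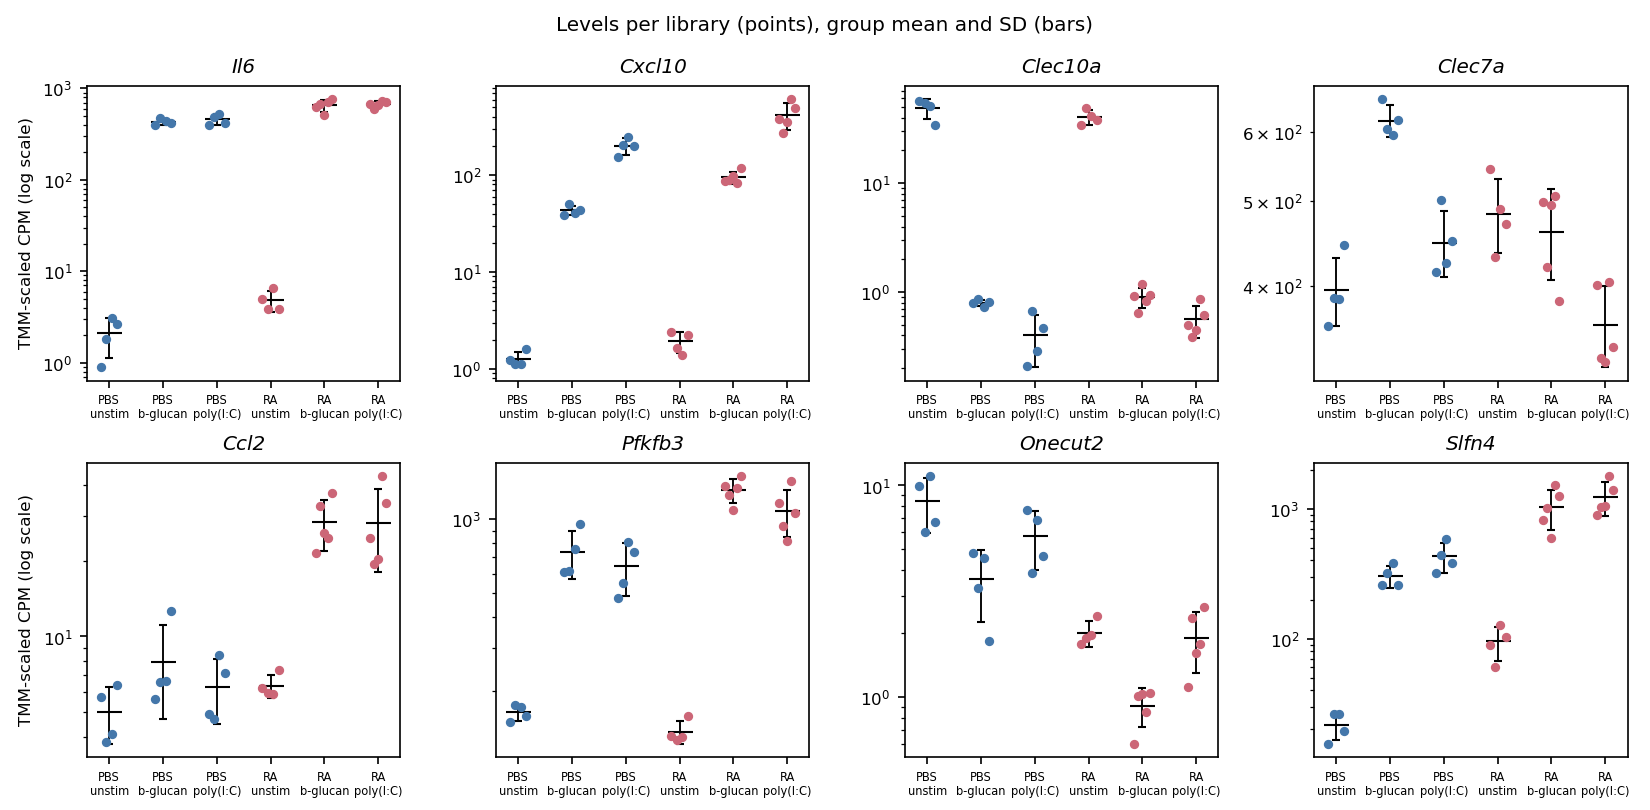
TMM-scaled CPM (log axis) of 8 genes in each library of the 6 groups, blue for PBS and red for RA mice, with group mean and SD. Slfn4 and Cxcl10 were highest in RA mice under poly(I:C) (1240 and 422 CPM), and Ccl2 averaged 28.4 and 28.3 CPM in RA mice under beta-glucan and poly(I:C).

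Between RA and PBS cells under beta-glucan, Rn7s2 (1.95 ± 0.31), F13a1 (1.93 ± 0.47), Rn7s1 (1.88 ± 0.26), Ccl2 (1.85 ± 0.25), Slfn4 (1.78 ± 0.26), Ackr3 (1.71 ± 0.56), Iigp1 (1.61 ± 0.19), Serpine1 (1.59 ± 0.41), Cmpk2 (1.54 ± 0.21) and Rsad2 (1.53 ± 0.22) rose most. Ccl2 (ENSMUSG00000035385.5, chromosome 11, 82035571 to 82037453), a monocyte attractant, had 28.4 ± 6.47 CPM in RA (n = 5) and 7.89 ± 3.2 in PBS mice (SD, n = 4; edgeR adjusted p = 3.12e-05), and Iigp1 and Cmpk2 are interferon-induced. Onecut2 (-1.99 ± 0.28), Fhdc1 (-1.88 ± 0.25), Tespa1 (-1.86 ± 0.30), Hsd11b2 (-1.71 ± 0.18), Scin (-1.59 ± 0.19), Mpzl2 (-1.58 ± 0.17) and Atp2a3 (-1.52 ± 0.19) fell most, of which Fhdc1 and Scin code for actin regulators and Tespa1 for a calcium-signalling adaptor. Slfn4 had 1040 ± 359 against 303 ± 58.1 CPM.

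Within the interferon-stimulated genes, 29 of 31 rose (31 adjusted over the list alone, median 0.58, camera adjusted p = 5.95e-31, 0.0771 with an estimated correlation). Mx1 (0.92 ± 0.10) and Xaf1 (0.57 ± 0.07) came first. Of the nucleic acid sensing genes, 11 rose and 3 fell of 17 (11 and 3 adjusted over the list alone, median 0.34, camera adjusted p = 8.52e-06, 0.137 with an estimated correlation). Ifih1 (0.65 ± 0.07) and Zbp1 (0.59 ± 0.08) came first. Of the inflammatory cytokines, 8 rose and 2 fell of 20 (9 and 2 adjusted over the list alone, median 0.50, camera adjusted p = 0.002, 0.204 with an estimated correlation). Il15 (0.78 ± 0.10) and Tnfsf10 (0.88 ± 0.17) led. Of the chemokines, 11 rose and 1 fell of 19 (11 and 1 adjusted over the list alone, median 0.58, camera adjusted p = 2.19e-08, 0.137 with an estimated correlation), with Cxcl10 (1.13 ± 0.18) and Ccl24 (1.40 ± 0.23) after Ccl2. In the inflammasome list 11 of 12 rose (12 adjusted over the list alone, median 0.48, camera adjusted p = 1.31e-09, 0.137 with an estimated correlation). Casp4 (0.63 ± 0.08) and Mefv (1.09 ± 0.17) came first. In the glycolysis list 14 of 16 rose (14 adjusted over the list alone, median 0.55, camera adjusted p = 7.78e-10, 0.228 with an estimated correlation). Gapdh (0.72 ± 0.11), Pfkfb3 (0.84 ± 0.16) and Pfkl (0.60 ± 0.13) came first. Pfkfb3 (ENSMUSG00000026773.19, chromosome 2, 11471433 to 11554077) had 1310 ± 149 against 736 ± 163 CPM. Of the macrophage markers, 5 rose and 1 fell of 16 (7 and 1 adjusted over the list alone, median 0.37, camera adjusted p = 0.015, 0.54 with an estimated correlation). Fcgr1 (1.03 ± 0.18) and Lyz2 (0.80 ± 0.17) came first. Of the dendritic cell identity genes, 2 rose and 8 fell of 16 (3 and 8 adjusted over the list alone, median -0.35, camera adjusted p = 0.00889, 0.213 with an estimated correlation). Kmo (-1.21 ± 0.14) came first.

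Of the C-type lectin pathway genes under beta-glucan, 6 rose and 1 fell of 15 (8 and 1 adjusted over the list alone, median 0.37, camera adjusted p = 0.00415, 0.506 with an estimated correlation). Mrc1 (0.99 ± 0.20) came first, while the beta-glucan receptor gene Clec7a (ENSMUSG00000079293.11, chromosome 6, 129461591 to 129472779) fell (-0.42 ± 0.09, edgeR adjusted p = 0.00167), with 461 ± 55.1 against 617 ± 25.8 CPM. Of the alternative activation list, 5 rose and 1 fell of 15 (7 and 2 adjusted over the list alone, median 0.26, camera adjusted p = 0.015, 0.467 with an estimated correlation), and of the MHC class II presentation genes, 1 rose and 3 fell of 13 (1 and 3 adjusted over the list alone, median -0.19, camera adjusted p = 0.0292, 0.54 with an estimated correlation). H2-Ob (-0.73 ± 0.14) came first. Of the dendritic cell maturation genes, 2 rose and 7 fell of 17 (2 and 9 adjusted over the list alone, median -0.25, camera adjusted p = 0.0321, 0.54 with an estimated correlation). Il15ra (0.59 ± 0.11) came first. Of the MHC class I presentation genes, 4 of 16 rose (4 adjusted over the list alone, median 0.13, camera adjusted p = 0.0208, 0.54 with an estimated correlation). In the cholesterol efflux and lysosomal lipid handling list 6 of 16 rose (7 adjusted over the list alone, median 0.38, camera adjusted p = 0.002, 0.467 with an estimated correlation). Npc2 (0.61 ± 0.12) and Apoe (1.37 ± 0.31) came first. In the unfolded protein response list 2 rose and 1 fell of 16 (2 and 1 adjusted over the list alone, median 0.18, camera adjusted p = 0.0481, 0.54 with an estimated correlation). Of the B cell markers, 1 of 7 fell (1 adjusted over the list alone, median -0.84, camera adjusted p = 0.0481, 0.233 with an estimated correlation).

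Further anchors under beta-glucan were Il6 (0.61 ± 0.18), Il10 (0.97 ± 0.25), Isg15 (0.53 ± 0.14), Ccl5 (0.58 ± 0.12), Nos2 (0.95 ± 0.27) and Tlr3 (0.99 ± 0.18), which rose, and Il12b (-0.81 ± 0.20), Cd86 (-0.40 ± 0.11) and Ccr7 (-0.43 ± 0.15), which fell, whereas Tnf (0.17 ± 0.14), Il1b (0.38 ± 0.17), Ifnb1 (0.67 ± 0.47), Arg1 (1.32 ± 0.50), Cd40 (-0.11 ± 0.15) and H2-Ab1 (-0.09 ± 0.12) did not pass. By edgeR 1990 genes rose and 2014 fell. With library totals 1634 rose and 2750 fell, and with the small RNA share as a covariate 1888 and 1143. The count of 4004 was 2406 without SKG_PBS_betaGlu replicate 1.

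**Figure D3:**
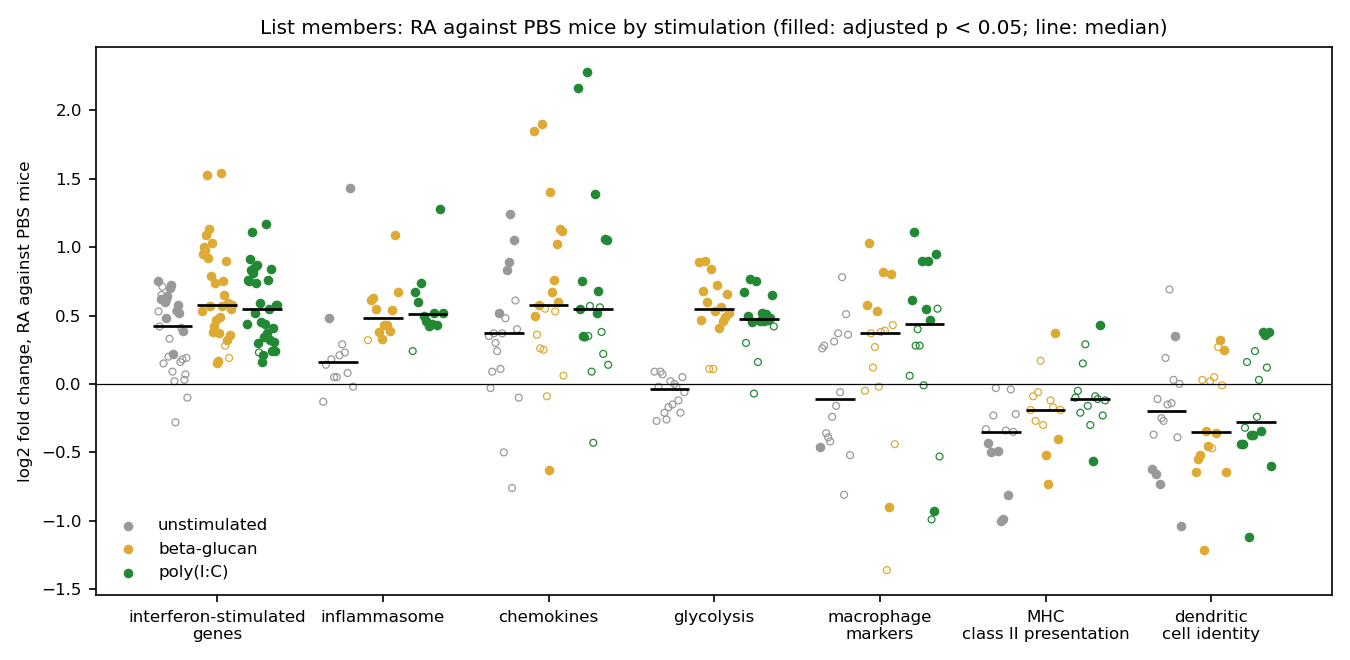
RA against PBS log2 fold changes (y axis) of the members of 7 gene lists in unstimulated, beta-glucan and poly(I:C) cells, filled where the edgeR adjusted p was under 0.05, with the list median as a line. The median of the interferon-stimulated genes was 0.42, 0.58 and 0.55, and that of the glycolysis genes -0.04, 0.55 and 0.48, the first of which was 0.03 with library totals.

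Between RA and PBS cells under poly(I:C), Ccl2 (2.16 ± 0.26), Rn7s2 (2.01 ± 0.31), Rn7s1 (2.00 ± 0.25), F13a1 (1.72 ± 0.47), Hp (1.64 ± 0.32), Saa3 (1.62 ± 0.34), Slfn4 (1.52 ± 0.25), Fcgr4 (1.45 ± 0.37), Retnla (1.42 ± 0.37) and Ccl24 (1.39 ± 0.23) rose most, of which Hp codes for haptoglobin and Retnla for a product of alternatively activated macrophages. Ccl2 had 28.3 ± 10.2 CPM (n = 5) against 6.32 ± 1.81 (SD, n = 4; edgeR adjusted p = 1.66e-05), Slfn4 1240 ± 361 against 431 ± 113 and Pfkfb3 1080 ± 232 against 644 ± 155 CPM. Fhdc1 (-2.24 ± 0.25), Onecut2 (-1.60 ± 0.26), Scin (-1.48 ± 0.19), Tespa1 (-1.41 ± 0.29), Mpzl2 (-1.39 ± 0.17), Atp2a3 (-1.37 ± 0.18) and Prnp (-1.20 ± 0.20) fell most, of which Prnp codes for the prion protein.

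As for the interferon-stimulated genes, 30 of 31 rose (31 adjusted over the list alone, median 0.55, camera adjusted p = 7.08e-25, 0.0896 with an estimated correlation). Mx1 (0.81 ± 0.10), Oasl2 (0.59 ± 0.09) and Isg20 (0.84 ± 0.13) came first. Of the nucleic acid sensing genes, 10 rose and 1 fell of 17 (12 and 1 adjusted over the list alone, median 0.29, camera adjusted p = 2.49e-06, 0.142 with an estimated correlation). Ifih1 (0.61 ± 0.07) and Zbp1 (0.57 ± 0.08) came first. Of the inflammatory cytokines, 9 rose and 3 fell of 20 (11 and 3 adjusted over the list alone, median 0.39, camera adjusted p = 0.000836, 0.179 with an estimated correlation). Il15 (0.74 ± 0.10) and Il10 (1.64 ± 0.28) came first. Of the chemokines, 10 rose and 0 fell of 19 (13 and 1 adjusted over the list alone, median 0.55, camera adjusted p = 4.81e-08, 0.145 with an estimated correlation), with Cxcl10 (1.06 ± 0.18) after Ccl2. In the inflammasome list 11 of 12 rose (11 adjusted over the list alone, median 0.51, camera adjusted p = 7.79e-12, 0.0896 with an estimated correlation). Mefv (1.28 ± 0.17) and Casp4 (0.60 ± 0.08) led. In the glycolysis list 12 of 16 rose (13 adjusted over the list alone, median 0.48, camera adjusted p = 3.64e-07, 0.299 with an estimated correlation), led by Pfkfb3 (0.75 ± 0.16), Gapdh (0.52 ± 0.11) and Ldha (0.65 ± 0.15), and 5 rose without the libraries of mouse numbers 43 to 45. Of the macrophage markers, 7 rose and 1 fell of 16 (8 and 1 adjusted over the list alone, median 0.43, camera adjusted p = 0.000523, 0.299 with an estimated correlation). Fcgr1 (1.11 ± 0.18), Mafb (0.90 ± 0.15) and Lyz2 (0.95 ± 0.17) came first. Of the C-type lectin pathway genes, 11 rose and 1 fell of 15 (11 and 1 adjusted over the list alone, median 0.50, camera adjusted p = 2.88e-05, 0.271 with an estimated correlation). Fcer1g (0.59 ± 0.13) came first.

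In the alternative activation list under poly(I:C) 8 rose and 0 fell of 15 (9 and 2 adjusted over the list alone, median 0.56, camera adjusted p = 0.000433, 0.22 with an estimated correlation), with Mgl2 (1.01 ± 0.17) after Ccl24. In the cholesterol synthesis list 7 rose and 1 fell of 20 (8 and 1 adjusted over the list alone, median 0.19, camera adjusted p = 0.00314, 0.474 with an estimated correlation). Lss (0.41 ± 0.09) came first. In the cholesterol efflux and lysosomal lipid handling list 6 of 16 rose (8 adjusted over the list alone, median 0.43, camera adjusted p = 3.96e-05, 0.271 with an estimated correlation). Plin2 (0.81 ± 0.16) and Npc2 (0.59 ± 0.12) came first. Among the MHC class I presentation genes, 4 of 16 rose (5 adjusted over the list alone, median 0.15, camera adjusted p = 0.00185, 0.472 with an estimated correlation). Psmb10 (0.55 ± 0.10) came first. Of the B cell markers, 1 of 7 fell (1 adjusted over the list alone, median -0.51, camera adjusted p = 0.0311, 0.218 with an estimated correlation). Further anchors were Il6 (0.54 ± 0.18), Isg15 (0.44 ± 0.14), Ccl5 (0.35 ± 0.12) and Tlr3 (0.92 ± 0.18), which rose, and Il12b (-0.91 ± 0.20) and Clec7a (-0.31 ± 0.09), which fell, the last with 361 ± 38.4 against 448 ± 38.4 CPM. Tnf (0.38 ± 0.14), Il1b (0.35 ± 0.17), Ifnb1 (0.74 ± 0.40), Arg1 (1.21 ± 0.50), Nos2 (0.74 ± 0.27), Cd40 (0.01 ± 0.15), Ccr7 (-0.31 ± 0.15) and H2-Ab1 (-0.05 ± 0.12) did not pass. By edgeR 1708 genes rose and 1399 fell. With library totals 1439 rose and 1931 fell, and with the small RNA share as a covariate 1892 and 908. The count of 3107 was 1502 without SKG_PBS_PolyIC replicate 1.

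The difference between RA and PBS mice was partly shared by the 3 conditions. Slfn4, Saa3, Rn7s1, Mefv, Hp and Apoe were among 133 genes higher in RA mice in all 3, and Onecut2, Mpzl2, Tespa1 and Scin among 367 lower in all 3, the genes being picked from the ends of that list. Under beta-glucan and poly(I:C) 1198 genes were higher in RA mice in both (181.3 if independent) and 1116 lower in both (150.3 if independent). The libraries of these 2 stimuli were correlated by mouse-number triple (r from 0.18 to 0.66 in PBS mice, above 0.1 in 4 of 5 RA pairs), so independence is not a fair baseline.

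Whether RA cells responded differently to a stimulus was asked by the difference between responses. For beta-glucan, 91 genes gained more and 27 less in RA mice. Rpgrip1 (1.81 ± 0.37), Pecam1 (1.57 ± 0.32), Car12 (1.5 ± 0.34), Ccl2 (1.5 ± 0.36), Bcar1 (1.45 ± 0.32), Rilpl1 (1.41 ± 0.24), F2r (1.37 ± 0.31), Ifi205 (1.37 ± 0.25), Plpp1 (1.32 ± 0.20) and Hdac9 (1.28 ± 0.31) were ahead, of which Pecam1 and F2r code for an adhesion molecule and the thrombin receptor. Cd1d1 (-1.01 ± 0.20), Adpgk (-0.98 ± 0.14), Slc9a5 (-0.82 ± 0.18), Tle1 (-0.78 ± 0.18), Agrn (-0.74 ± 0.12), Pot1b (-0.74 ± 0.15), Lrp4 (-0.73 ± 0.17) and Clec7a (-0.72 ± 0.13) were at the other end, of which Cd1d1 presents lipids. Clec7a went from 395 ± 35.6 to 617 ± 25.8 CPM in PBS mice, and had 483 ± 46.9 unstimulated and 461 ± 55.1 CPM with beta-glucan in RA mice (edgeR adjusted p = 0.0126 for the difference). Ccl2 had 5.02 ± 1.27 unstimulated in PBS and 6.37 ± 0.672 CPM in RA mice.

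Of the glycolysis genes, 2 of 16 had a positive difference that passed (15 adjusted over the list alone, median 0.60, camera adjusted p = 2.43e-15, 0.537 with an estimated correlation). Gapdh (0.86 ± 0.16) and Pfkfb3 (1.09 ± 0.22) came first, and fry gave an adjusted p of 0.0975. Of the macrophage markers, by edgeR 0 passed, 6 lay higher and 0 lower at an unadjusted p under 0.05, DESeq2 called 1 and limma-voom 0 (median 0.43, camera adjusted p = 0.00179, 0.566 with an estimated correlation). Unstimulated Pfkfb3 had 164 ± 11.9 CPM in PBS and 137 ± 14.6 in RA mice. Across the interferon-stimulated genes, 2 of 31 responded more (7 adjusted over the list alone, median 0.20, camera adjusted p = 2.47e-06, 0.566 with an estimated correlation), with Mx1 (0.77 ± 0.14) and Usp18 (0.78 ± 0.15). Of the MHC class I presentation genes, 1 of 16 responded more (3 adjusted over the list alone, median 0.21, camera adjusted p = 0.000433, 0.566 with an estimated correlation), with Tap1 (0.46 ± 0.10). Anchors that did not pass included Il6 (-0.58 ± 0.28), Tnf (0.26 ± 0.20), Il1b (-0.50 ± 0.25) and Il12b (-0.59 ± 0.30), and no fold is given for Il10 and Ifnb1, which had 2 and 0 unstimulated counts in PBS mice. At an unadjusted p under 0.05 there were 2488 genes. With library totals the median shifted by -0.12, and the difference was positive for 35 genes and negative for 68.

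The beta-glucan count of 118 depended on the model and on single libraries. It was 1038 with mouse-number triples as a fixed block and 489 as a random block, 920 with voom quality weights, 397 with the DESeq2 Wald test, 307 with only its groups and 272 with the Malat1 share as a covariate. It was 28, 54 and 75 without SKG_PBS_Unstim replicates 1, 2 and 3, and 22, 20, 53 and 222 without SKG_PBS_betaGlu replicates 1 to 4. It was 76 without SKG_PBS_PolyIC replicate 4 and 21, 61, 58 and 42 without SKG_RA_Unstim replicates 1 to 4. It was 52 and 54 without SKG_RA_betaGlu replicates 1 and 5, and 301 and 70 without SKG_RA_PolyIC replicates 4 and 5.

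For poly(I:C), the difference was positive for 81 genes and negative for 13. Ccl2 (1.81 ± 0.36), Itgae (1.60 ± 0.35), Plpp1 (1.48 ± 0.20), Asb2 (1.44 ± 0.28), Emp1 (1.40 ± 0.29), F2r (1.39 ± 0.32), Ifi205 (1.37 ± 0.25), Rilpl1 (1.27 ± 0.24), Clec4a1 (1.22 ± 0.22) and Rasal1 (1.18 ± 0.24) were ahead, of which Ifi205 belongs to an interferon-induced DNA sensor family, and Tasp1 (-1.11 ± 0.24), Cd1d1 (-0.90 ± 0.20), Adpgk (-0.80 ± 0.14), Rapgef5 (-0.72 ± 0.16), Agrn (-0.71 ± 0.12) and Arg2 (-0.68 ± 0.13) behind. Of the glycolysis genes, 2 of 16 responded more (12 adjusted over the list alone, median 0.54, camera adjusted p = 1.83e-10, 0.27 with an estimated correlation), again Pfkfb3 (1.01 ± 0.22) and Gapdh (0.67 ± 0.16), and fry gave an adjusted p of 0.0641. Of the macrophage markers, 1 of 16 had a positive difference (7 adjusted over the list alone, median 0.53, camera adjusted p = 2.38e-05, 0.27 with an estimated correlation), Mafb (1.14 ± 0.21), a macrophage transcription factor gene. Among the interferon-stimulated genes, 2 of 31 responded more (4 adjusted over the list alone, median 0.18, camera adjusted p = 0.0072, 0.711 with an estimated correlation). Of the MHC class II presentation genes, 1 of 13 had a positive difference (3 adjusted over the list alone, median 0.33, camera adjusted p = 2.25e-05, 0.27 with an estimated correlation), Ciita (0.70 ± 0.16). Unadjusted p values under 0.05 numbered 2222, and with library totals the median shifted by -0.12 and 19 gained more and 16 less. The count of 94 was 867 with mouse-number triples as a fixed block and 278 as a random block, 247 with voom quality weights, 288 with the DESeq2 Wald test, 20 with only its groups and 159 with the Malat1 share. It was 30 and 62 without SKG_PBS_Unstim replicates 1 and 2, and 26, 45, 208 and 45 without SKG_PBS_PolyIC replicates 1 to 4. It was 37, 25 and 51 without SKG_RA_Unstim replicates 1, 3 and 4, and 46 and 36 without SKG_RA_PolyIC replicates 4 and 5. Without the libraries of mouse numbers 43 to 45 it was 33. Pfkfb3 (0.87 ± 0.23, adjusted p = 0.126) and Gapdh (0.68 ± 0.17, adjusted p = 0.109) then missed the threshold, and the glycolysis median was 0.42.

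Poly(I:C) was set directly against beta-glucan to separate the stimuli. In PBS mice Cxcl10 (2.22 ± 0.19), Pla2g4f (1.85 ± 0.22), Oprd1 (1.72 ± 0.21), M1ap (1.65 ± 0.26), Cmpk2 (1.55 ± 0.22), Scube3 (1.48 ± 0.25) and Rsad2 (1.47 ± 0.23) were higher with poly(I:C), of which Pla2g4f codes for a phospholipase and Oprd1 for an opioid receptor. Hamp (-2.79 ± 0.24), Il33 (-1.87 ± 0.23), Il18rap (-1.82 ± 0.17), Edn1 (-1.79 ± 0.25), Il18r1 (-1.75 ± 0.29), Cd6 (-1.75 ± 0.23) and Rhou (-1.70 ± 0.27) were lower, of which Hamp codes for the iron hormone hepcidin, Il33 for an alarmin and Edn1 for endothelin. Within the interferon-stimulated genes, 24 of 31 were higher (28 adjusted over the list alone, median 0.48, camera adjusted p = 2.03e-33, 0.0598 with an estimated correlation). Oasl1 (1.38 ± 0.12) and Mx1 (0.99 ± 0.10) came first. Of the inflammatory cytokines, 8 were higher and 2 were lower of 20 (9 and 4 adjusted over the list alone, median 0.17, camera adjusted p = 0.0419, 0.429 with an estimated correlation), with Il10 (-2.71 ± 0.29) and Csf3 (-3.67 ± 0.40) first and Il15 (0.90 ± 0.10) and Il12b (1.27 ± 0.21) next. Of the C-type lectin pathway genes, 5 of 15 were lower (6 adjusted over the list alone, median -0.41, camera adjusted p = 5.06e-05, 0.429 with an estimated correlation), with Mrc1 (-1.52 ± 0.22), Cd209a (-2.46 ± 0.49), Card9 (-0.43 ± 0.09) and Clec7a (-0.46 ± 0.10). Of the osteoclast genes, 0 were higher and 4 were lower of 12 (1 and 4 adjusted over the list alone, median -0.41, camera adjusted p = 0.00587, 0.314 with an estimated correlation). Atp6v0d2 (-0.90 ± 0.12) and Itgb3 (-1.85 ± 0.30) came first. Of the monocyte and myeloid progenitor markers, 0 were higher and 4 were lower of 15 (1 and 4 adjusted over the list alone, median -0.46, camera adjusted p = 0.048, 0.429 with an estimated correlation). Ccr2 (-1.21 ± 0.20) came first. By edgeR 866 genes were higher and 1234 lower, 551 and 2478 with library totals.

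In RA mice Cxcl10 (2.15 ± 0.17), Pla2g4f (1.82 ± 0.20), Oprd1 (1.70 ± 0.19), M1ap (1.70 ± 0.24), Scube3 (1.70 ± 0.23), Tnfrsf11b (1.54 ± 0.21) and Tnnt2 (1.54 ± 0.33) were higher with poly(I:C) than with beta-glucan, and Hamp (-2.56 ± 0.21), Cyp26b1 (-1.91 ± 0.21), Il33 (-1.89 ± 0.20), Kazald1 (-1.81 ± 0.31), Mrc1 (-1.68 ± 0.19), Edn1 (-1.62 ± 0.22) and Gpnmb (-1.52 ± 0.17) lower. Cxcl10 had 422 ± 131 against 94.7 ± 13.4 CPM (SD, n = 5 each; edgeR adjusted p = 5.65e-09). As for the interferon-stimulated genes, 24 of 31 were higher (27 adjusted over the list alone, median 0.40, camera adjusted p = 2.69e-23, 0.234 with an estimated correlation). Oasl1 (1.19 ± 0.10) and Mx1 (0.88 ± 0.09) came first. Of the dendritic cell maturation genes, 7 were higher and 1 were lower of 17 (11 and 2 adjusted over the list alone, median 0.38, camera adjusted p = 9.56e-06, 0.448 with an estimated correlation). Icosl (1.11 ± 0.08), Cd40 (0.79 ± 0.14) and Cd86 (0.50 ± 0.11) came first, all costimulators. Among the MHC class I presentation genes, 10 of 16 were higher (11 adjusted over the list alone, median 0.30, camera adjusted p = 9.55e-07, 0.483 with an estimated correlation). Nlrc5 (0.62 ± 0.09) and Tap2 (0.37 ± 0.07) came first. Of the C-type lectin pathway genes, 3 of 15 were lower (3 adjusted over the list alone, median -0.23, camera adjusted p = 0.00166, 0.635 with an estimated correlation), with Mrc1 (-1.68 ± 0.19), Cd209a (-2.09 ± 0.39) and Clec7a (-0.35 ± 0.09). Of the osteoclast genes, 1 were higher and 5 were lower of 12 (2 and 6 adjusted over the list alone, median -0.37, camera adjusted p = 0.0352, 0.483 with an estimated correlation). Atp6v0d2 (-0.65 ± 0.11) and Ctsk (-0.77 ± 0.15) came first, and Ctsk is a bone-degrading protease gene. Of the cell cycle genes, 7 of 26 were lower (8 adjusted over the list alone, median -0.22, camera adjusted p = 0.000556, 0.636 with an estimated correlation). Cenpf (-0.93 ± 0.17) and Bub1 (-0.53 ± 0.10) came first. By edgeR 1398 genes were higher and 1474 lower, 892 and 2666 with library totals.

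Of the non-coding RNAs, Rn7s1, the RNA of the signal recognition particle, had 12.4 ± 3.49 CPM (SD, n = 14, 8.12 to 21) in RA and 3.47 ± 0.967 CPM (n = 12, 2.04 to 4.56) in PBS libraries, without overlap. The 6 small RNA genes Rn7s1, Rn7s2, Rn7sk, Rmrp, Rpph1 and Rprl3 together had 3650 ± 837 CPM (1960 to 5040) in RA and 1790 ± 301 CPM (1450 to 2400) in PBS libraries. Malat1, a nuclear long non-coding RNA, had 13500 ± 3020 CPM (8140 to 17400) in RA and 11000 ± 1490 CPM (7800 to 12700) in PBS libraries. The last 2 ranges overlapped.

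**Figure D4:**
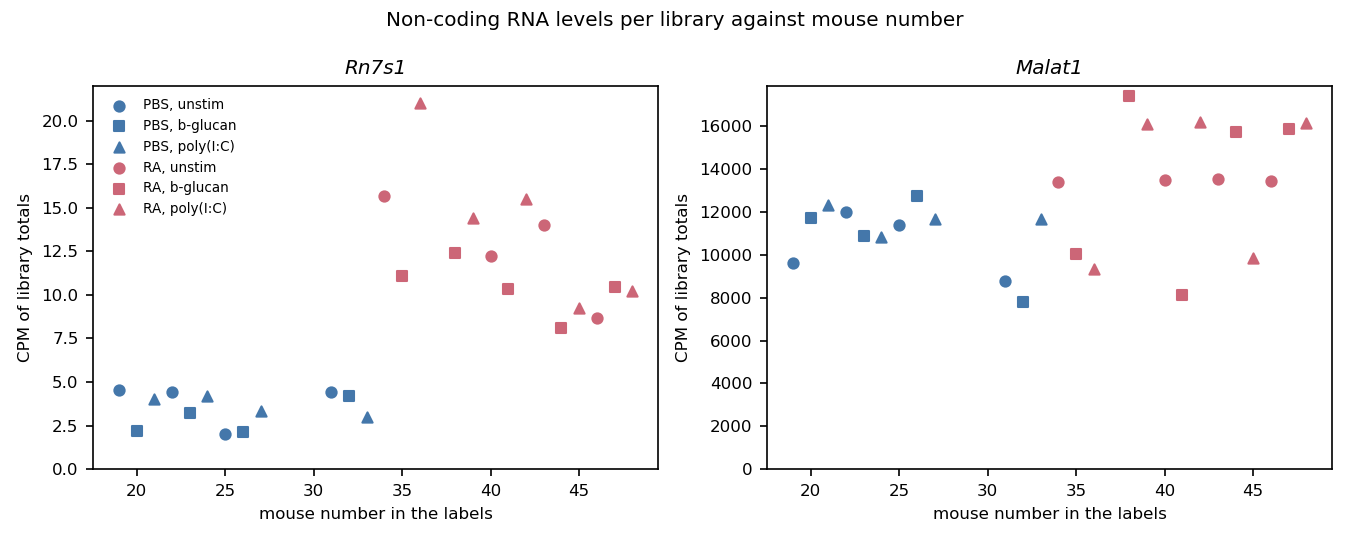
CPM of library totals of Rn7s1 and Malat1 in each library (y axis) by mouse number (x axis), blue for PBS and red for RA mice. Rn7s1 lay at 8.12 to 21 CPM in RA and at 2.04 to 4.56 CPM in PBS libraries.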

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

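The tests with the small RNA share, the Malat1 share, mouse numbers 43 to 45, the ranges of mouse numbers, the macrophage markers and the headings of the CPM table, and the counts over other splits of the libraries, paired or not, were chosen after the results had been seen.

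Single libraries lay far from the rest of their group in 3 of 72 groups of levels and library measures, where chance marks about 1 in 20. Ccl2 had 12.6 CPM in SKG_PBS_betaGlu replicate 4, Pfkfb3 had 159 CPM in SKG_RA_Unstim replicate 4, and Rn7s1 had 2.04 CPM in SKG_PBS_Unstim replicate 3.

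The response to beta-glucan differed between RA and PBS mice in 118 genes by edgeR (20 to 301 with 1 library left out). On the log2 scale the differences that passed were 1.81 for Rpgrip1, 1.57 for Pecam1, 1.5 for Car12 and for Ccl2, 1.45 for Bcar1, 1.41 for Rilpl1, 1.37 for F2r and for Ifi205, 1.32 for Plpp1, 1.28 for Hdac9, 1.09 for Pfkfb3, 0.86 for Gapdh, 0.78 for Usp18, 0.77 for Mx1 and 0.46 for Tap1. In the other direction they were -1.01 for Cd1d1, -0.98 for Adpgk, -0.82 for Slc9a5, -0.78 for Tle1, -0.74 for Agrn and for Pot1b, -0.73 for Lrp4, -0.72 for Clec7a, -0.67 for C2cd2 and -0.66 for Sort1. Lists whose difference passed camera with the preset correlation had medians of 0.60 for glycolysis, 0.43 for macrophage markers, 0.40 for alternative activation, 0.31 for the inflammasome, 0.30 for cholesterol efflux, 0.22 for nucleic acid sensing, MHC class II and cell cycle, 0.21 for MHC class I and 0.20 for interferon-stimulated genes. None passed with an estimated correlation. More alternative activation, MHC class II and cell cycle genes fell than rose, so a positive difference can be a smaller fall.

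The response to poly(I:C) differed in 94 genes (25 to 208 with 1 library left out). The differences were 1.81 for Ccl2, 1.60 for Itgae, 1.48 for Plpp1, 1.44 for Asb2, 1.40 for Emp1, 1.39 for F2r, 1.37 for Ifi205, 1.27 for Rilpl1, 1.22 for Clec4a1, 1.18 for Rasal1, 1.14 for Mafb, 1.01 for Pfkfb3, 0.87 for Klf4, 0.72 for Usp18, 0.70 for Ciita, 0.67 for Gapdh, 0.65 for Mx1 and 0.46 for Tap1. In the other direction they were -1.11 for Tasp1, -0.90 for Cd1d1, -0.80 for Adpgk, -0.72 for Rapgef5, -0.71 for Agrn, -0.68 for Arg2, -0.66 for Fam126a and for Dgat1, -0.61 for Clec7a and -0.50 for Ttc7b. List medians were 0.55 for alternative activation, 0.54 for glycolysis, 0.53 for macrophage markers, 0.36 for C-type lectins, the inflammasome and osteoclast genes, 0.34 for monocyte and progenitor markers, 0.33 for MHC class II and cholesterol efflux, 0.25 for MHC class I and cholesterol synthesis, 0.18 for interferon-stimulated genes and 0.17 for nucleic acid sensing. None passed with an estimated correlation. A smaller fall is possible here for alternative activation, C-type lectins, monocyte markers and MHC class II.

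Of 31 interferon-stimulated genes, 13, 29 and 30 were higher in RA than in PBS mice without stimulus, with beta-glucan and with poly(I:C) (medians 0.42, 0.58 and 0.55), and camera's adjusted p = 0.279, 0.0771 and 0.0896 with an estimated correlation lost the list's calls. With the small RNA share as covariate the median was 0.59, 0.81 and 0.75, but the share tracked treatment, so a trend is not excluded. More macrophages among the sorted RA cells could not be excluded: the macrophage markers had medians of -0.11 (SD 0.45 over markers), 0.37 (SD 0.63) and 0.43 (SD 0.64) against 0.42, 0.58 and 0.55 for the interferon-stimulated genes, the gaps of 0.53, 0.21 and 0.11 shrank to 0.24, 0.01 and -0.13 at the lowest with the added settings, and that criterion was tightened after the values had been seen, while its first version would have excluded macrophages. A mouse batch or preparation that differed between RA and PBS mice and the injection itself cannot be told apart, because 0 libraries of either treatment had a mouse number inside the range of the other. A lasting effect of zymosan or of the arthritis may underlie the difference and stays untested against these.

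Of 16 glycolysis genes, 2 responded more in RA mice to each stimulus, with list medians of 0.60 for beta-glucan and 0.54 for poly(I:C). Camera's adjusted p with an estimated correlation was 0.537 and 0.27, and fry's was 0.0975 and 0.0641. With the Malat1 share as a covariate the poly(I:C) median was 0.49, and without the libraries of mouse numbers 43 to 45 it was 0.42, so neither accounted for the whole of it. Without those 3 libraries the genes that passed for poly(I:C) went from 2 to 0, with 0.87 ± 0.23 for Pfkfb3 (1.01 ± 0.22 before) and 0.68 ± 0.17 for Gapdh (0.67 ± 0.16 before), whose fold held while its unadjusted p went from 0.000239 to 0.000479 with fewer libraries. The macrophage markers moved alongside (medians 0.43 and 0.53), and since neither a larger macrophage share nor a batch was tested here, an altered metabolic response after zymosan may be weighed only as a hypothesis.

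In the deposited CPM table, 21 of 26 headings stood over the counts of another library and 16 over those of another stimulus, including 5 of the 8 unstimulated headings. In 26 of 26 columns the values scaled the counts of the library next in order of mouse number, which is consistent with headings in group order set over columns in mouse-number order. No biological explanation was tested. The headings were not used for any group.

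Other splits of the same libraries were counted with limma's trend on log2 CPM. Against unstimulated cells the real split alone, 1 of 35, reached its count for beta-glucan (11491, highest other 1) and poly(I:C) (12285, highest other 4) in PBS mice. It was 1 of 100 in RA mice for beta-glucan (12092, highest other 10343) and poly(I:C) (12506, highest other 10799). Those others were near-mirrors of the real split. Triples may pair these libraries (r up to 0.51), which leaves too few splits to exclude chance. For RA against PBS, unpaired, chance was excluded at 1 of 35 unstimulated (1134, highest other 2). It was 1 of 100 with beta-glucan (4020, highest other 2542, replicates 3 exchanged) and poly(I:C) (3194, highest other 2275, a near-mirror). The splits for differences between responses exchanged RA and PBS labels, so the RA against PBS difference entered the test or its spread. They cannot decide whether the responses differ. For beta-glucan 3 of 100 called as many (122, highest other 2053). That other split kept most resting labels and exchanged nearly all RA and PBS labels of stimulated libraries. For poly(I:C) it was 1 of 100 (98, highest other 23). For poly(I:C) against beta-glucan in PBS mice it was 1 of 35 (2145, highest other 213). Replicate numbers pair these libraries, though, and the 8 splits that part all 4 pairs (highest other 1) are too few for a share under 0.05. It was 2 of 100 in RA mice (2982, highest other 3143). The latter put the stimulated libraries of mouse numbers 44 and 45 on one side, so a structure among these libraries was not excluded.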

How the results depend on the processing

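Results are given in the order beta-glucan and poly(I:C) against unstimulated in PBS and then in RA mice, RA against PBS mice unstimulated, with beta-glucan and with poly(I:C), the differences between beta-glucan and between poly(I:C) responses, and poly(I:C) against beta-glucan in PBS and in RA mice. Counts not listed stayed within 1.5 times their own value of 11467, 12191, 12033, 12400, 1124, 4004, 3107, 118, 94, 2100 and 2872. Except where a stricter threshold, fewer genes or fewer libraries make the cause plain, the cause was not tested.

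A log2 fold change of at least 1 left 5412, 6187, 5622, 6102, 196, 528, 310, 29, 28, 361 and 421 genes. An adjusted p under 0.01 left 384, 2068 and 1505 for RA against PBS mice, 11 and 12 for the differences between responses, and 994 and 1498 for poly(I:C) against beta-glucan. The authors' CPM under its own headings gave 0, 0, 0, 0, 51, 4, 211, 0, 0, 0 and 0 by limma's trend (80, 72, 64, 188, 1184, 479, 1588, 149, 161, 36 and 236 at an unadjusted p under 0.05, of 11307 genes), with headings, genes, scaling and test all changed at once.

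RA against PBS unstimulated cells, the difference for beta-glucan and the difference for poly(I:C) gave 1707, 397 and 288 genes with the DESeq2 Wald test, 2197, 307 and 20 with only the groups in the contrast, and 2818, 920 and 247 with voom quality weights. With triples of mouse numbers as a fixed block the differences gave 1038 and 867, and as a random block (correlation 0.166) 489 and 278. The Malat1 share gave 272 and 159. Library totals gave 35 for the poly(I:C) difference, and the fit without mouse numbers 43 to 45 gave 33. The small RNA share gave 235 for unstimulated RA against PBS cells. Poly(I:C) against beta-glucan gave 1686 in RA mice with only its groups and 3237 in PBS mice with quality weights. In PBS mice the block by replicate gave 2183 and the block by triples 3136, within 1.5 times 2100. The slopes of the RA on the PBS response, 0.953 and 0.925, were 0.894 and 0.873 without a filter and 0.982 and 0.953 with a stricter filter. With an estimated correlation 23 of 119 camera calls held.

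With each library left out, the counts ran from 10926 to 11570, 11670 to 12316, 11472 to 12147, 11872 to 12519, 519 to 1281, 2406 to 4644, 1502 to 3312, 20 to 301, 25 to 208, 1449 to 2413 and 2172 to 3758, and the slopes from 0.932 to 0.963 and from 0.904 to 0.935, lowest for poly(I:C) without SKG_PBS_PolyIC replicate 3. Among 813 pairs of named gene and comparison, 533 of 21138 such refits lost a call and 0 reversed. Of the 645 called pairs, 102 lost the call under 1 or more alternatives other than a threshold, and 1 of all pairs reversed: H2-Ab1 for poly(I:C) in RA mice had -0.13 with library totals in place of 0.35. Small shifts in genes near the floor and genes with near-identical copies are the limits that depth and counting set, and 52.0 to 80.8 M counts per library left rare cytokines such as Ifnb1 at 0 to 8 unstimulated counts per group.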

Other observations

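The test of whether RA cells lie further along a stimulus response was written before its result was seen, and the genes and lists of the next paragraph follow lists fixed beforehand but were picked for their values.

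Lists that did not pass camera for beta-glucan in PBS mice still held genes that passed. Of the oxidative phosphorylation genes 1 rose and 14 fell of 20 (2 and 14 adjusted over the list alone, median -0.41, camera adjusted p = 0.0641). Of the cholesterol synthesis genes 3 rose and 12 fell of 20 (4 and 12 adjusted over the list alone, median -0.33, camera adjusted p = 0.0593), with the last sterol step Dhcr7 (-2.59 ± 0.12) lowest. Of the osteoclast genes 7 rose and 4 fell of 12 (7 and 5 adjusted over the list alone, median 0.91, camera adjusted p = 0.338), with Acp5 (3.27 ± 0.18), a phosphatase of bone-resorbing cells. The iron-binding antimicrobial gene Lcn2 (7.24 ± 0.32) and the growth-factor receptor gene Csf3r (2.05 ± 0.18) rose within the neutrophil and granulocyte precursor markers, where 3 rose and 3 fell of 14 (3 and 3 adjusted over the list alone, median -0.14 and mean 0.27, camera upward adjusted p = 0.843). Il1rl1, the receptor of Il33, fell within the mast cell and basophil markers (-7.82 ± 0.25), while histamine-forming Hdc (7.03 ± 0.20) rose, and 2 rose and 1 fell of 5 (2 and 1 adjusted over the list alone, median 0.04 and mean -0.11 and -0.23 with library totals, camera upward adjusted p = 0.972). Within the T and NK cell markers 1 rose and 2 fell of 4 (1 and 2 adjusted over the list alone, median -0.76 and mean -0.37, camera upward adjusted p = 0.972). Within the fibroblast and stromal markers 4 rose and 2 fell of 8 (4 and 2 adjusted over the list alone, median 1.28, camera adjusted p = 0.441), and of the erythroid list Ermap alone was measured, which rose (1.85 ± 0.46). Trem2, a lipid receptor of macrophages, fell with beta-glucan in PBS mice (-3.59 ± 0.22) and was higher in RA than in PBS mice under it (0.86 ± 0.20). The stem cell factor receptor gene Kit was lower in RA mice in all 3 conditions (-0.87 ± 0.15, -0.70 ± 0.14 and -0.57 ± 0.14), as was Cd34 (-1.17 ± 0.17, -0.72 ± 0.16 and -0.74 ± 0.16).

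Cells of RA mice may lie further along a stimulus response even at rest. Across 11619 genes the RA against PBS differences would then follow it, at an r of 0.2 or more. In unstimulated cells, with the controls split between both sides, r lay between -0.01 and 0.1 for the beta-glucan and between -0.01 and 0.11 for the poly(I:C) response over 6 ways of halving. It was 0 with beta-glucan cells against the poly(I:C) response and -0.08 with poly(I:C) cells against the beta-glucan response. Noise lowers r and errors shared by triple move it, so values under 0.2 do not decide.

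Mitochondrial genes had 0 counts in every library. Even counts made up 64.8% of values from 1 to 10, 53.9% from 11 to 50, 50.1% from 51 to 200 and 49.8% above that, up to 1000, so small counts were even more often than odd. No pair of libraries within a group was a duplicate, with chi-square per gene from 12.68 to 183.91 over 44 pairs.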
